A study of Mus musculus with 22 samples.

How the data were processed

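Total cerebellar RNA from 22 female mice was measured on Affymetrix mouse expression arrays, 1 array per mouse. The labels name the mice as biological replicates. The Sca1 table holds 12 arrays, with 3 knock-in and 3 wild-type mice at 4 weeks and 3 of each genotype at 9 to 12 weeks. In the older Sca1 group, replicate 4 of each genotype was 9 weeks old and replicates 5 and 6 were 12 weeks old. The Sca7 table holds 10 arrays, with 5 knock-in and 5 wild-type mice at 5 weeks. The lines were measured on different array types. The labels give C57BL/6J as the strain of the mice, with backcrossing over several generations.

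Both tables hold deposited probe set values on a log2 scale. The submitters' processing notes name GCOS 1.1. The background correction, normalization and summary method behind the log-scale values is not given in the sources used here. The base of the logarithm is not stated either, and base 2 was inferred from the range of the deposited values. The array medians ran from 6.08 to 6.21 on the log2 scale in the Sca1 table and from 6.87 to 6.99 in the Sca7 table. Both tables list the same 22690 probe sets, of which 64 control probe sets were left out, which left 22626. The deposited log2 values were used without rescaling, and each table was fitted by itself.

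Each probe set was joined to a gene by the symbol in the annotation supplied with the arrays. There were 20380 probe sets with 1 symbol, 691 with several symbols and 1555 with none, and only those with 1 symbol were used. They covered 12393 genes, and for the 4956 genes with several probe sets the probe set with the highest mean was kept. Probe sets in the lowest 25% by mean value, under 2.80 in the Sca1 table and 2.71 in the Sca7 table, were left out. This kept 9452 genes in the Sca1 table and 9488 in the Sca7 table, of which 8998 were shared.

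Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend). All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. The Sca1 fit had 1 mean per genotype and age group and a spread shared by all 12 arrays, with 8 residual degrees of freedom and 4.23 prior degrees of freedom. The same fit gave the genotype contrast at each age, the mean of both, the difference between them, and the age contrast within wild-type mice. The Sca7 fit compared the genotypes with 8 residual and 3.47 prior degrees of freedom. Fold changes are knock-in minus wild type, or older minus younger, on the log2 scale. The number of arrays limits the precision of every value.

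Before the data were examined, 26 gene lists were fixed from general knowledge, with 610 gene names of which 522 matched a measured gene. They cover Purkinje cells, granule cells, GABAergic interneurons, Bergmann glia and astrocytes, myelin, oligodendrocyte precursors, microglia, endothelial and mural cells, choroid plexus, meningeal fibroblasts, midbrain and hindbrain neighbours and red blood cells. The others cover metabotropic glutamate and calcium signalling, potassium and sodium channels, GABA and glycine receptors, synaptic vesicles, the insulin-like growth factor pathway, Capicua targets, chaperones, the proteasome, cholesterol synthesis, immediate early genes, the integrated stress response, oxidative phosphorylation, the cell cycle and granule progenitors, and the interferon response. The midbrain and hindbrain list and the red blood cell list had fewer than 5 measured genes and were not tested, which left 24. Each list was tested with limma's camera at a preset correlation of 0.01, which compares its genes with all others, and adjusted over the 24 lists. Each was also tested with camera at an estimated correlation and with fry, which asks only whether the genes of a list move, on balance, one way. Members passing over all genes tested and members passing when adjusted over the list alone were counted separately.

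The genes named in the text follow a rule written at the same time as the lists. It names Atxn1 and Atxn7, then Igf1, Igf2, Igf1r, Igfbp2, Igfbp3, Igfbp4, Igfbp5 and Igfbp7. In each genotype comparison it takes the 10 genes with the largest rise and the 10 with the largest fall among those that passed. Where fewer than 5 passed in a direction, it fills up to 5 by the smallest p and calls them not passing. For the difference between ages and the age comparison it takes 5 in each direction, for each list described the 4 members with the smallest p, and for genes shared between lines the 10 in each direction with the smallest larger p. Symbols of unnamed clones and expressed sequences were passed over.

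The fold changes of both lines were compared across the 8998 shared genes, which are not independent replicates. The 100 genes with the smallest p in each direction in 1 line were tested as lists in the other. The share of called genes on the chromosome of the targeted gene was tested with Fisher's exact test, with gene positions from the RefSeq annotation of GRCm38.p6. For the counts of genes and lists called, the mice were also regrouped. All 10 ways were used for 3 against 3 mice, and 100 drawn ways otherwise. Of single lists, only the Purkinje median in the mean of both ages and the top Sca1 list downward in Sca7 mice were regrouped. So were the correlations between lines and between ages.

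The scripts were tested on simulated data drawn with each gene's mean and residual spread and no correlation between genes, with 200 changed genes in each of 10 sets. With a change of 1.5-fold, 50.9% of the changed genes were recovered at 4 weeks, 57.9% at 9 to 12 weeks, 80.4% for the mean of both ages and 87.9% in the Sca7 table. At 1.25-fold these shares were 11%, 12.1%, 38.5% and 57.3%. False calls made up 3.92% to 5.88% of all calls, and a list shifted by -0.3 was called in 10 of 10 sets. Other lists were called 0.2 to 0.9 times per set. Genes were drawn without correlation, so these sets cannot show how often lists are falsely called in the arrays themselves. There, other groupings of the mice called a median of 4 to 7 lists per comparison.

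The alternatives were quantile normalization, median centring, other filters, other handling of several probe sets per gene, no intensity trend, array weights, exact age, only the 12-week mice, a replicate block, other thresholds, other list tests and leaving out each array in turn. Chosen after the data were seen were a fit without both 9-week mice, a Sca7 fit without wild-type replicates 2 and 4 and knock-in replicate 5, and the calcium signalling list without the members it shares with the Purkinje list. Probe sets with several symbols or none and the control probe sets were not used here.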

Results

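Expression was measured in the cerebellum of mice that carry an expanded CAG repeat in Atxn1 (Sca1 knock-in) or in Atxn7 (Sca7 knock-in), and in wild-type mice of each line. These genes encode ataxin-1 and ataxin-7, the proteins expanded in spinocerebellar ataxia types 1 and 7, and the labels place the mice at an early symptomatic stage. The Sca1 mice formed 4 groups of 3, knock-in and wild type at 4 weeks and at 9 to 12 weeks. The Sca7 mice formed 2 groups of 5 at 5 weeks. Each mouse was measured on 1 array. Values are deposited log2 values, and differences are knock-in minus wild type unless another direction is named.

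The first comparison asked which transcripts differed between Sca1 knock-in and wild-type cerebellum at 9 to 12 weeks. As a list, markers of Purkinje cells were lower in the knock-in mice, by amounts that differed between markers. Rgs8, a regulator of G protein signalling that is abundant in Purkinje cells, fell by 0.50, from 13.09 ± 0.134 in wild type to 12.60 ± 0.0710 in knock-in mice (mean ± SD, n = 3 each). Doc2b, a calcium sensor of transmitter release, fell by 0.79, from 9.49 ± 0.104 to 8.70 ± 0.245 (n = 3 each). Of the genes that passed, the deepest falls were in Th, the rate-limiting enzyme of catecholamine synthesis, by 1.37, from 5.58 ± 0.128 to 4.21 ± 0.202, and in Hsd3b7, an enzyme of bile acid synthesis, by 1.28, from 6.71 ± 0.0800 to 5.43 ± 0.165 (n = 3 each). Clstn2, a synaptic membrane protein of the cadherin superfamily, fell 2.38-fold, from 8.61 ± 0.0580 to 7.36 ± 0.143 (n = 3 each).

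Of 9452 genes, 14 passed in limma at 9 to 12 weeks, 1 upward and 13 downward, and 869 had an unadjusted p under 0.05 where chance gives 473. The adjusted p was 0.00228 for Th and Clstn2, 0.0147 for Hsd3b7, 0.0328 for Rgs8 and 0.0402 for Doc2b. The gene that rose was Marcks, an actin-binding substrate of protein kinase C, by 0.62 from 10.95 ± 0.109 to 11.57 ± 0.158 (n = 3 each, adjusted p = 0.0402). Nab2, a corepressor of Egr transcription factors, fell by 1.18 (adjusted p = 0.0187), and Tuba8, an alpha-tubulin, fell by 0.71 (adjusted p = 0.0115). Plvap, a protein of endothelial diaphragms, fell by 1.14, from 8.00 ± 0.256 to 6.87 ± 0.206 (n = 3 each). Plvap, Plxdc1, a transmembrane protein found in endothelium, and Col18a1, a basement membrane collagen, each had an adjusted p of 0.0391, with falls of 0.80 for Plxdc1 and 0.74 for Col18a1. Twsg1, a secreted binding protein of bone morphogenetic proteins, fell by 0.79 (adjusted p = 0.0402). The rises of Fcgr2b (0.79), Robo1 (0.65), Calb2 (0.46) and Synpr (0.83) did not pass, with adjusted p of 0.0501, 0.0558, 0.0723 and 0.0723. Without knock-in replicate 4 these 4 passed, with adjusted p of 0.0383, 0.0177, 0.0375 and 0.00734. Without knock-in replicates 1, 2, 3, 4, 5 and 6 in turn, 5, 6, 5, 152, 2 and 2 genes passed, and without wild-type replicates 1, 3, 5 and 6 in turn, 6, 5, 2 and 3. Th and Clstn2 stayed under 0.05 in all 12 such fits, and the count was 5 under quantile normalization and 258 with array weights.

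**Figure D1:**
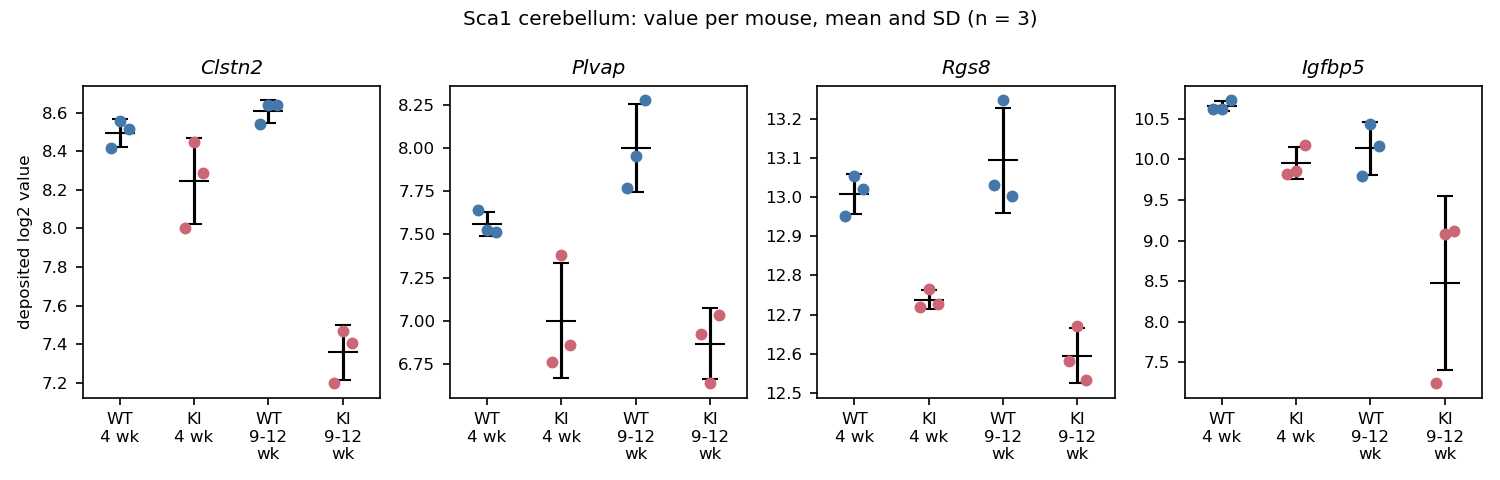
Deposited log2 values of Clstn2, Plvap, Rgs8 and Igfbp5 per Sca1 mouse (y axis, own scale for each gene) in wild-type (WT, blue) and knock-in (KI, red) mice at 4 and 9 to 12 weeks, with the mean and SD of each group in black (n = 3). At 9 to 12 weeks the knock-in mean of Clstn2 was 7.36 against 8.61 in wild type.

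Among the fixed lists, the Purkinje cell markers fell as a group at 9 to 12 weeks, with a median of -0.32 and 21 of 23 measured members below 0. Over all genes 2 members fell (Rgs8 and Doc2b), and adjusted over the list alone 14 fell and 1 rose. The differences were smaller in Calb1 (-0.18), Pcp2 (-0.13), Car8 (-0.12) and Rora (-0.04). Slc1a6 (0.04) and Ebf1 (0.40) lay above 0. Lhx1, a homeodomain transcription factor of Purkinje cells, was at -0.47, and the kinase Stk17b at -0.50, with adjusted p over all genes of 0.0723 and 0.0742. The camera adjusted p was 9.1e-12, and this was the list whose call held with an estimated correlation (adjusted p = 0.0486 with an estimated correlation, and 0.00377 in fry). The metabotropic glutamate and calcium signalling list fell too, with a median of -0.28 and 26 of 30 members below 0 (camera adjusted p = 8.64e-10; adjusted p = 0.138 with an estimated correlation). None of its members passed over all genes, and 9 fell adjusted over the list alone, among them Inpp5a (-0.41) and Itpka (-0.59), which remove inositol trisphosphate, the phospholipase Plcb3 (-0.78) and the calmodulin-binding Pcp4 (-0.41). It shares 6 members with the Purkinje list, and without them, an alternative chosen after seeing the data, its adjusted p was 1.01e-07. Potassium and sodium channels fell with a median of -0.21 and 18 of 24 members below 0 (adjusted p = 0.000852; adjusted p = 0.138 with an estimated correlation). Of these 4 fell adjusted over the list alone, Kcnip1 (-0.58), Kcnma1 (-0.83), Kcnj9 (-0.49) and Kcnc1 (-0.52), and 0 over all genes. In fry 5 lists were called at this age, those of Purkinje cells, calcium signalling, channels, interneurons, and GABA and glycine receptors. Bergmann glia (fry adjusted p = 0.0783), meningeal fibroblasts (0.237), myelin (0.306), Capicua targets (0.306) and oxidative phosphorylation (0.695) were not.

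Lists of other cell types fell in the same arrays. Myelin markers had a median of -0.25 with 18 of 20 members below 0 (adjusted p = 0.000639; adjusted p = 0.501 with an estimated correlation), and Mal, a myelin membrane protein, at -0.55, was the member that fell adjusted over the list alone. Bergmann glia and astrocyte markers had a median of -0.16 with 20 of 25 below 0 (adjusted p = 0.0123; adjusted p = 0.254 with an estimated correlation), and Gdf10 (-0.45) fell adjusted over the list alone. Meningeal fibroblast markers had a median of -0.23 with 11 of 12 below 0 (adjusted p = 0.0290; adjusted p = 0.362 with an estimated correlation), and Islr (-0.71) fell adjusted over the list alone. GABAergic interneuron markers had a median of -0.14 with 12 of 14 below 0 (adjusted p = 0.0275; adjusted p = 0.138 with an estimated correlation). Their member Cck, a neuropeptide, fell by 0.60 over all genes, from 9.27 ± 0.0824 to 8.67 ± 0.149 (n = 3 each, limma adjusted p = 0.0399). GABA and glycine receptors had a median of -0.14 with 7 of 8 below 0 (adjusted p = 0.0289; adjusted p = 0.144 with an estimated correlation), and Gabbr1 (-0.27) fell adjusted over the list alone. Without knock-in replicate 4 the adjusted p was 0.0792 for myelin, 0.413 for interneurons, 0.6254 for meningeal fibroblasts and 0.123 for the receptors. The medians, in the same order, were then -0.2244, -0.1948, -0.1768 and -0.1998, so these lists lost their call and kept their direction. Without wild-type replicate 5 it was 0.187 for interneurons, 0.235 for meningeal fibroblasts, and 0.0866 for the receptors and for Bergmann glia. Without knock-in replicate 6 it was 0.0832 for the receptors and for Bergmann glia, and without wild-type replicate 4 it was 0.0903 for the receptors.

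The lists that rose at 9 to 12 weeks were Capicua targets and oxidative phosphorylation. Capicua is a transcriptional repressor that binds ataxin-1, and its targets had a median of 0.10 with 8 of 10 members above 0 (adjusted p = 0.0275; adjusted p = 0.362 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The largest differences by p were in Etv4 (0.42), Spry4 (0.43), Dusp6 (0.33) and Ccnd1 (0.13). Oxidative phosphorylation genes had a median of 0.04 with 29 of 43 above 0 (adjusted p = 0.0275; adjusted p = 0.799 with an estimated correlation), and no member passed over all genes or over the list alone. Their members with the smallest p were Cox7c (-0.61), Cox6c (0.22), Uqcrb (0.19) and Ndufb9 (0.17). For Capicua targets the adjusted p was 0.0763, 0.117, 0.192 and 0.136 without knock-in replicates 4 and 5 and wild-type replicates 4 and 6 in turn. For oxidative phosphorylation it was 0.123, 0.612, 0.187 and 0.0891 without knock-in replicates 4 and 6 and wild-type replicates 5 and 6 in turn. The medians of that list were then 0.006, -0.003, 0.004 and 0.042, so its sign turned without knock-in replicate 6.

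The other 14 lists were not called at 9 to 12 weeks. The medians and adjusted p were -0.09 and 0.174 for cholesterol synthesis, -0.19 and 0.215 for microglia, -0.04 and 0.485 for the integrated stress response, and 0.00267 and 0.485 for oligodendrocyte precursors. They were -0.08 and 0.486 for chaperones, -0.02 and 0.561 for endothelial and mural cells, -0.08 and 0.561 for the insulin-like growth factor pathway, and -0.02 and 0.610 for immediate early genes. They were 0.02 and 0.610 for synaptic vesicles, -0.01 and 0.801 for choroid plexus, 0.03 and 0.935 for the cell cycle and granule progenitors, -0.00600 and 0.935 for the proteasome, 0.01 and 0.968 for the interferon response, and -0.06 and 0.987 for granule cells. For choroid plexus the median and mean lay below 0 while the test pointed upward. For synaptic vesicles, the cell cycle and the interferon response the mean lay below 0 and the median above. Adjusted over the list alone, single members passed in several of these lists, among them the myeloid receptor Csf1r (-0.56) and Ly86 (-0.65) among microglia, Gli1 (-0.55), a transcription factor of the hedgehog pathway, Sox4 (0.63) among precursors, Msmo1 (-0.63) in cholesterol synthesis, and Calb2 (0.46) among granule cells.

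**Figure D2:**
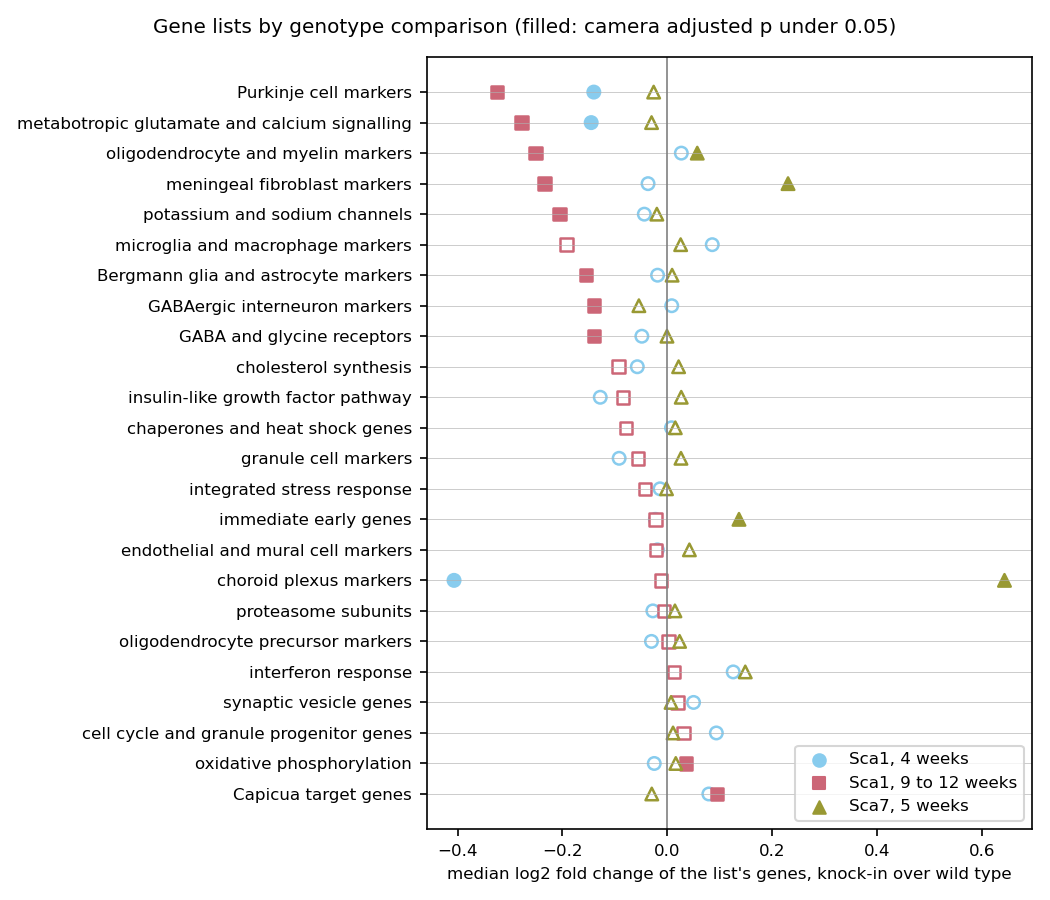
Median log2 fold change of each of 24 fixed gene lists, knock-in over wild type (x axis), in Sca1 mice at 4 weeks (circles) and 9 to 12 weeks (squares) and in Sca7 mice (triangles), filled where the camera adjusted p was under 0.05. The Purkinje cell list lay at -0.32 in the older Sca1 mice and at -0.03 in the Sca7 mice.

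At 4 weeks, the Purkinje cell list was lower in Sca1 knock-in mice, with a median of -0.14 and 20 of 23 members below 0, while no single gene passed. The Purkinje list had a camera adjusted p of 8.48e-05 (adjusted p = 0.503 with an estimated correlation, and 0.281 in fry). Lhx1 was at -0.50 (9.61 ± 0.130 in knock-in against 10.10 ± 0.110 in wild type, n = 3 each) and Rgs8 at -0.27 (12.74 ± 0.0248 against 13.01 ± 0.0520, n = 3 each), and both fell adjusted over the list alone. The metabotropic glutamate and calcium signalling list fell with a median of -0.15 and 27 of 30 members below 0 (adjusted p = 0.000628; adjusted p = 0.669 with an estimated correlation), with Inpp5a at -0.28, Itpka at -0.37, Pcp4 at -0.24 and Cacna2d2 at -0.27, of which 0 passed over all genes or over the list alone. Without the members shared with the Purkinje list its adjusted p was 0.00152, and without knock-in replicate 2 that of the whole list was 0.103. Choroid plexus markers fell with a median of -0.41 and 11 of 11 members below 0 (adjusted p = 0.0115; adjusted p = 0.937 with an estimated correlation), and 0 members passed over all genes or over the list alone. Knock-in replicate 1 had a mean of 4.88 over this list, where the other knock-in mice had 5.68 and 6.20 and the wild-type mice 5.79 to 6.07. Without knock-in replicate 1 the choroid plexus median was -0.04 and its adjusted p 0.836, and without wild-type replicates 2 and 3 in turn the adjusted p was 0.0653 and 0.0525.

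In limma, 0 of 9452 genes passed at 4 weeks, 543 had an unadjusted p under 0.05 where chance gives 473, and the smallest adjusted p was 0.640. The genes with the smallest p upward were Faap24 (0.77), Ccdc85a (0.61), Mettl21a (0.65), Apoc1 (0.46) and Ppfibp2 (0.66), and downward Lhx1, Gli1 (-0.50), Kank2 (-0.76), Tuba8 (-0.43) and Rdh5 (-0.71). None of them passed. Their adjusted p ran from 0.640 to 0.735, and without knock-in replicate 1 a single gene passed. Adjusted over the list alone, Gli1 fell among cell cycle and granule progenitor genes, and Nkx6-2 (0.35) rose among myelin markers. Of the 21 lists not called, granule cells came nearest, with a median of -0.09 and an adjusted p of 0.0756. That list was called down with exact age (0.0192), without both 9-week mice (0.0177), without a filter (0.00218), and without knock-in replicates 3 and 4 and wild-type replicate 4 in turn (0.00633, 0.0461 and 0.0481), while with an estimated correlation its adjusted p was 0.669. The medians of Bergmann glia (-0.02) and microglia (0.09) had the opposite sign of the means of these lists.

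Averaged over both ages, the genes named here fell or rose in Sca1 knock-in mice and passed. Plvap fell by 0.85, Th by 0.82, Hsd3b7 by 0.79, Nab2 by 0.76, Clstn2 by 0.75, Plxdc1 by 0.66, Tuba8 by 0.57 and Col18a1 by 0.56. Inhbb, a subunit of activins and inhibins, fell by 0.79, and the adaptor protein Stap2 by 0.56. F2r, a thrombin receptor, rose by 0.68, Spock1, a matrix proteoglycan, by 0.61, Fcgr2b, an inhibitory receptor for immunoglobulin G, by 0.56, and Robo1, a receptor for Slit proteins, by 0.55. Mettl21a rose by 0.54, Marcks by 0.43, Hmgn3 by 0.35 and Mboat2 by 0.33.

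In limma 33 of 9452 genes passed for this mean (6 against 6 mice), 8 upward and 25 downward, and the adjusted p of the named genes ran from 0.00726 for Clstn2 and Tuba8 to 0.0421 for Mettl21a. A total of 1219 genes had an unadjusted p under 0.05. Without knock-in replicates 1, 2, 3, 4 and 6 in turn, 11, 13, 21, 200 and 10 genes passed, and without wild-type replicates 1, 2, 3, 5 and 6 in turn, 11, 10, 5, 8 and 7. Th, Clstn2 and Tuba8 stayed under 0.05 in all 12 such fits, with 0.0361 as the highest adjusted p. Each of the 8 genes that rose lost its call in at least 1 of these fits. Their highest adjusted p ran from 0.0720 for Robo1 to 0.137 for Mettl21a. Without knock-in replicate 6, 0 genes passed upward. Of the named genes, F2r, Robo1, Th and Inhbb lay in the dimmer 50% of the probe sets. Of the other probe sets of the called genes, 18 pointed the same way and 4 the opposite way, those of Ipo5, Mettl21a, Rhou and Washc2. F2r and Spock1 lie on the chromosome of Atxn1.

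The Purkinje list had a median of -0.25 with 22 of 23 members below 0 in the mean of both ages (camera adjusted p = 5.76e-10; adjusted p = 0.0792 with an estimated correlation, 0.00256 in fry). Over all genes 3 of its members fell, Lhx1 (-0.48), Rgs8 (-0.38) and Doc2b (-0.55), and adjusted over the list alone 14 fell and 1 rose. The metabotropic glutamate and calcium signalling list had a median of -0.19 with 28 of 30 below 0 (adjusted p = 1.37e-08; adjusted p = 0.213 with an estimated correlation). Inpp5a (-0.34) and Itpka (-0.48) fell over all genes, and 6 members fell adjusted over the list alone. Potassium and sodium channels had a median of -0.10 with 18 of 24 below 0 (adjusted p = 0.0261; adjusted p = 0.445 with an estimated correlation), with 4 members that fell and 1 that rose adjusted over the list alone. Without knock-in replicates 2 and 6 and wild-type replicate 5 in turn, the channel list had adjusted p of 0.0507, 0.0748 and 0.0579, and without both 9-week mice 0.0605. The other 21 lists were not called, with adjusted p from 0.195 to 0.735. Beside these lists, the medians of myelin (-0.11), meningeal fibroblast (-0.15), choroid plexus (-0.20) and endothelial markers (0.00783) had adjusted p of 0.195, 0.206, 0.274 and 0.550. For endothelial markers the mean and the test pointed downward, and for oligodendrocyte precursors, with a median of -0.04, the mean and the test pointed upward.

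Insulin-like growth factor genes were a named set of interest. Igfbp5, a secreted binding protein of insulin-like growth factors, was lower by log2 -1.65 in Sca1 knock-in mice at 9 to 12 weeks, 8.48 ± 1.07 against 10.13 ± 0.321 (n = 3 each, 95% interval -2.48 to -0.82). It did not pass over all genes (limma adjusted p = 0.150) and fell adjusted over the list alone (0.0215). At 4 weeks Igfbp5 was at -0.70 (9.96 ± 0.196 against 10.66 ± 0.0624, n = 3 each), and in the mean of both ages at -1.18 (95% interval -1.76 to -0.59, adjusted p = 0.103, and 0.0204 over the list alone). Without knock-in replicate 4 the older difference was -1.03 and Igfbp5 passed (adjusted p = 0.0136, and 0.00749 in the mean of both ages). It also passed at 9 to 12 weeks with exact age (0.0108), with only the 12-week mice (0.00901) and without both 9-week mice (0.00826), and in the mean of both ages with exact age (0.00904) and without both 9-week mice (0.00129). In Sca7 mice Igfbp5 was at -0.01 (95% interval -0.30 to 0.27). Igfbp6 (-0.37) and Foxo3 (-0.22) also fell adjusted over the list alone in the mean of both ages.

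None of the other named growth factor genes passed. In the mean of both ages Igf1 was at 0.25, Igf2 at -0.14, Igf1r at 0.01, Igfbp2 at -0.22, Igfbp3 at 0.03, Igfbp4 at 0.37 and Igfbp7 at -0.03, with adjusted p from 0.433 to 0.976. In Sca7 mice they were at -0.08, 0.23, 0.05, 0.40, -0.07, 0.15 and 0.27 in the same order, each with an adjusted p of 0.986 or more. Wild-type replicate 4 carried most of the Sca7 values of Igfbp2 and Igfbp4, which were 0.0565 and 0.0613 without it. The signs of Igf1r, Igfbp2, Igfbp3 and Igfbp7 in Sca1 mice turn under some alternatives, as do those of Igf1, Igf1r, Igfbp5 and Atxn7 in Sca7 mice. The Atxn1 probe set had a mean of 2.68 in the Sca1 table, under the filter, and was not tested. Atxn7 was at -0.17 at 4 weeks, -0.51 at 9 to 12 weeks (adjusted p = 0.588) and 0.12 in Sca7 mice (adjusted p = 0.987).

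The difference between ages was tested directly. No gene passed in limma (0 of 9452, 211 with an unadjusted p under 0.05, smallest adjusted p = 0.606), so no gene was shown to differ between ages in its genotype effect. Clstn2 (-0.999) and Th (-1.11) came nearest with adjusted p of 0.606, followed by Cck (-0.68), Thy1 (-0.63) and Dkk3 (-1.02), and upward by Fancl (0.85), Rraga (0.52), Hnrnpdl (0.31), Plod2 (0.94) and Hook2 (0.88), all with 0.999. Without knock-in replicate 1 a single gene passed. Across the 9452 genes, which are not independent replicates, the fold changes at both ages had a Pearson r of 0.440 and a Spearman rho of 0.464, and 13 of the 14 genes called at 9 to 12 weeks had the same sign at 4 weeks.

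By list, 9 differed between ages in camera. The genotype effect was more negative in older mice for myelin (median -0.30, adjusted p = 2.14e-05), Purkinje cells (-0.17, 0.00180), metabotropic glutamate and calcium signalling (-0.16, 0.00517), Bergmann glia (-0.15, 0.00877), channels (-0.21, 0.00877) and interneurons (-0.12, 0.0102). It was more positive for choroid plexus (0.38, 0.00517), oxidative phosphorylation (0.05, 0.00700) and granule cells (0.06, 0.0348). With an estimated correlation 0 of the 9 held, with adjusted p = 0.294 for Purkinje, Bergmann glia, channel, interneuron and granule cell lists, 0.369 for myelin and calcium signalling, 0.450 for choroid plexus and 0.610 for oxidative phosphorylation. No member of these lists passed over all genes, and Cck (-0.68) was the member that fell adjusted over the list alone. Without the members shared with the Purkinje list the calcium signalling list had an adjusted p of 0.0175. The meningeal fibroblast list (-0.18, 0.0673) was not called here, and was called among other settings with exact age (adjusted p = 0.0348).

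Each of the 9 calls of a difference between ages ended without at least 1 array. Without knock-in replicate 1 the adjusted p was 0.606 for choroid plexus, whose median turned to -0.0755, and 0.0599 for granule cells. Without knock-in replicate 2 it was 0.164 for myelin, 0.155 for granule cells and for interneurons, and 0.152 for Bergmann glia. Without knock-in replicate 3 it was 0.0925 for channels and 0.145 for oxidative phosphorylation. Without knock-in replicate 4 it was 0.220 for interneurons, 0.163 for calcium signalling, 0.0639 for channels and 0.0543 for oxidative phosphorylation. Without knock-in replicate 5 it was 0.426 for granule cells and 0.371 for choroid plexus. Without knock-in replicate 6 it was 0.0915 for Bergmann glia, 0.0585 for calcium signalling, 0.109 for channels and 0.401 for oxidative phosphorylation. Without wild-type replicate 1 it was 0.0535 for channels, without replicate 2 it was 0.0582 for granule cells, without replicate 3 it was 0.180 for oxidative phosphorylation and without replicate 4 it was 0.0963 for choroid plexus. Without wild-type replicate 5 it was 0.0891 for Purkinje cells, channels and oxidative phosphorylation, 0.0779 for granule cells, 0.134 for interneurons, 0.105 for Bergmann glia and 0.135 for calcium signalling. Without wild-type replicate 6 it was 0.0798 for granule cells.

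The age comparison in wild-type mice gives the difference between the age groups in the same table. On the first principal component of the Sca1 arrays, the 4-week arrays lay at -15.94 to -6.46 and the 12-week arrays at 2.37 to 11.69. The 9-week arrays lay farther out, at 22.79 and 16.05. Maturation therefore cannot be told apart from other differences between the arrays of each age. The myelin and cholesterol synthesis lists were lower at 9 to 12 weeks than at 4 weeks in camera (adjusted p = 0.0539 and 0.117 with an estimated correlation). Gsn, an actin-severing protein, fell by 1.62, from 11.34 ± 0.357 to 9.72 ± 0.0516, and Ugt8a, which makes the myelin lipid galactosylceramide, fell by 1.40, from 11.29 ± 0.103 to 9.89 ± 0.0713 (n = 3 each). Mog, a myelin surface protein, fell by 1.30 from 9.94 ± 0.237 to 8.64 ± 0.351 (n = 3 each). The collagens Col3a1 and Col4a2 fell by 2.68 and 2.28, and Fabp7, a fatty acid binding protein of glial progenitors, fell by 1.73. Il33, a cytokine of the interleukin-1 family, rose by 2.29 from 5.69 ± 0.968 to 7.98 ± 0.298, and the interferon-induced Ifit3 rose by 1.66 from 6.46 ± 0.511 to 8.13 ± 0.191 (n = 3 each).

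In limma 41 of 9452 genes passed for age, 19 upward and 22 downward, and 1199 had an unadjusted p under 0.05. Kazald1 (1.11), Sqor (0.99) and Wwc1 (0.97) were the next largest rises of genes that passed, and Necab3 (-2.02) and Mybpc3 (-1.82) were among the largest falls of such genes. The adjusted p of the named genes ran from 0.00617 to 0.0413. Of their other probe sets and those of the remaining called genes, 39 pointed the same way and 3 the opposite way, those of Cd93, Col3a1 and Nectin3. Without wild-type replicates 1, 3, 4, 5 and 6 in turn, 0, 0, 13, 9 and 11 genes passed, and without knock-in replicate 4 there were 65.

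The myelin list had a median of -0.67 with age, with 20 of 20 members below 0 (camera adjusted p = 6.48e-28; adjusted p = 0.0539 with an estimated correlation). Over all genes 6 members fell and adjusted over the list alone 17 did, among them Fa2h (-1.20). Cholesterol synthesis had a median of -0.41 with 19 of 19 below 0 (adjusted p = 1e-13; adjusted p = 0.117 with an estimated correlation), with Cyp51 (-1.01) passing over all genes and 6 members adjusted over the list alone, Hmgcs1 (-0.87), Dhcr7 (-0.94) and Sqle (-1.18) among them. The lists of granule cells (-0.14, adjusted p = 5.87e-05), oligodendrocyte precursors (-0.37, 0.00105), synaptic vesicles (-0.10, 0.00440), immediate early genes (-0.10, 0.00519), endothelial cells (-0.14, 0.00751), the insulin-like growth factor pathway (-0.06, 0.0367) and calcium signalling (-0.07, 0.0367) fell. Chaperones (0.18, 0.00608), choroid plexus (0.64, 0.00751) and the integrated stress response (0.15, 0.0238) rose, and Asns (0.39), an asparagine synthesis enzyme, passed over all genes in the last. With an estimated correlation the adjusted p were 0.0539 for granule cells, 0.117 for precursors, immediate early genes and endothelial cells, 0.185 for the stress response, 0.460 for chaperones, and 0.502 for the remaining 4 lists.

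Some age calls ended without 1 array. The adjusted p was 0.0721 for endothelial cells without wild-type replicate 3, 0.0602 for choroid plexus without wild-type replicate 5 and 0.131 for synaptic vesicles without wild-type replicate 4. It was 0.0582 and 0.0637 for the stress response without wild-type replicates 2 and 5. For the growth factor list it was 0.0552 without knock-in replicate 1 and 0.3001 and 0.3291 without wild-type replicates 3 and 4. For calcium signalling it was 0.122, 0.0823, 0.289 and 0.101 without wild-type replicates 2, 3, 4 and 6. Among the 12 lists not called for age, Purkinje cells had a median of 0.07 and an adjusted p of 0.7099, and meningeal fibroblasts a median of 0.12 with a mean of -0.29 and a test that pointed downward (0.410). The interferon response, with a median of 0.13, was not called here, and was called upward among other settings with exact age (adjusted p = 0.0491) and without both 9-week mice (0.00490).

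The Sca7 comparison asked which transcripts differed between knock-in and wild-type cerebellum at 5 weeks. No single gene passed. Meningeal fibroblast, immediate early, choroid plexus and myelin lists were called in camera, and with an estimated correlation 0 of these 4 held (adjusted p = 0.362, 0.452, 0.806 and 0.806). As many lists were called in 52 of 100 regroupings of the mice. Meningeal fibroblast markers rose, with a median of 0.23 and 12 of 13 members above 0, among them the collagens Col1a2 (0.37) and Col3a1 (0.70; 7.69 ± 0.491 in wild type and 8.40 ± 0.450 in knock-in, n = 5 each), Ogn (0.36) and Igf2 (0.23). Immediate early genes, which neuronal activity induces, rose with a median of 0.14 and 12 of 17 above 0, with Klf2 at 0.32, Dusp1 at 0.31, Nr4a1 at 0.34 and Fos at 0.64 (11.01 ± 0.605 and 11.66 ± 0.381, n = 5 each). Choroid plexus markers rose with a median of 0.64 and 11 of 11 above 0, with Aqp1 at 0.73, Folr1 at 0.90, Calml4 at 0.69 and Sostdc1 at 0.85. Myelin markers rose with a median of 0.06 and 17 of 20 above 0, with Gsn at 0.29, Gal3st1 at 0.16, Olig1 at 0.07 and Cnp at 0.06. No member of these 4 lists passed over all genes or adjusted over the list alone.

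The camera adjusted p in Sca7 mice were 4.16e-06 for meningeal fibroblasts (adjusted p = 0.362 with an estimated correlation), 0.00379 for immediate early genes (adjusted p = 0.452 with an estimated correlation), 0.00617 for choroid plexus and 0.0318 for myelin (each with adjusted p = 0.806 with an estimated correlation). Wild-type replicate 4 had a mean of 5.37 over the choroid plexus list, where the other wild-type mice had 7.57 to 7.77. Without it the choroid plexus median was 0.03 with an adjusted p of 0.545, and without knock-in replicate 4 the adjusted p was 0.0766. Immediate early genes had 0.0632 without wild-type replicate 1. Myelin had 0.0632 and 0.286 without wild-type replicates 1 and 2, and 0.361, 0.283 and 0.0902 without knock-in replicates 2, 4 and 5. With wild-type replicate 1 left out 2 lists were called, and with knock-in replicate 5 left out 8. Without wild-type replicates 2 and 4 and knock-in replicate 5 together, chosen after seeing the data for a low choroid plexus or a pituitary signal, 6 lists were called. Purkinje cells (median -0.05, adjusted p = 0.000661) and calcium signalling (-0.07, 0.000244) were downward, and choroid plexus (0.09, 0.000261), meningeal fibroblasts (0.19, 4.78e-05), immediate early genes (0.24, 1.53e-05) and the interferon response (0.16, 0.000244) upward. With an estimated correlation 0 of these 6 held (adjusted p = 0.0678 for calcium signalling and immediate early genes, 0.275 for choroid plexus, 0.389 for meningeal fibroblasts and 0.4555 for Purkinje cells and the interferon response). For the choroid plexus, immediate early, Purkinje and calcium signalling lists, wild-type replicate 2 and knock-in replicate 5 lay beyond the remaining mice of their own group on the side opposite to the call, so leaving them out pushes these lists toward it.

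In limma 0 of 9488 genes passed in the Sca7 mice, 350 had an unadjusted p under 0.05 where chance gives 474, and each named gene had an adjusted p of 0.986. The smallest p upward were those of Pabpc1 (0.17), Irf9 (0.54), Msto1 (0.45), B3gat1 (0.31) and Kdelr2 (0.24), and downward of Plaat1 (-0.52), Gad2 (-0.33), Zcchc7 (-0.26), Epm2aip1 (-0.32) and Peak1 (-0.47). Adjusted over the list alone, Irf9, a transcription factor of interferon signalling, rose in the interferon list (6.21 ± 0.204 to 6.76 ± 0.181, n = 5 each), whose median was 0.15 with an adjusted p of 0.0629. Gad2, which makes the transmitter GABA, fell in the interneuron list (7.50 ± 0.0942 to 7.17 ± 0.135, n = 5 each), whose median was -0.05 with an adjusted p of 0.1002. The Purkinje list had a median of -0.03 with 13 of 23 members below 0 and an adjusted p of 0.389. For the Capicua and stress response lists the median was below 0 and the mean above.

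**Figure D3:**
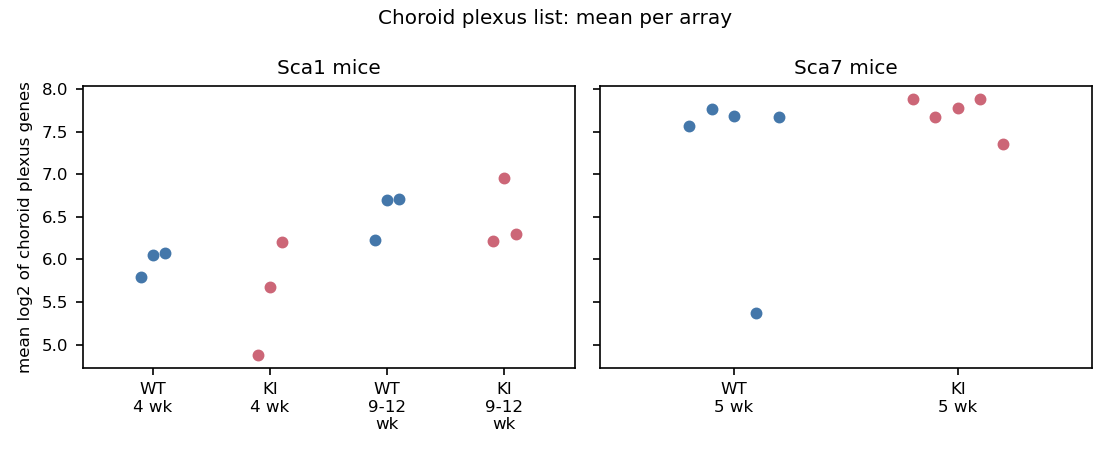
Mean deposited log2 value of the 11 choroid plexus markers per array (y axis) in Sca1 mice (left) and Sca7 mice (right), wild type (WT, blue) and knock-in (KI, red). Sca1 knock-in replicate 1 lay at 4.88 and Sca7 wild-type replicate 4 at 5.37, below the other arrays of each line.

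Both lines were compared over 8998 genes measured in each table, to ask which transcripts they share. The lines also differ in array type and in age, which cannot be told apart from the line. No gene passed in both lines, since 0 passed in Sca7 mice. Across genes, the Sca1 mean of both ages and the Sca7 fold changes had a Pearson r of 0.0524 and a Spearman rho of 0.0924. With the Sca1 fold changes at 4 weeks alone, the age nearer to that of the Sca7 mice, they were 0.03975 and 0.0881. Of the 33 Sca1 genes, 20 of the 25 that fell were below 0 in Sca7 mice, 6 of the 8 that rose were above 0, and 1 had an unadjusted p under 0.05 there, Fcgr2b. Fcgr2b was at 0.56 in Sca1 and 0.72 in Sca7 mice (4.75 ± 0.179 in wild type and 5.47 ± 0.494 in knock-in, n = 5 each). Over all genes, 28 had an unadjusted p under 0.05 in both lines in the same direction where chance gives 21.1, and 18 in opposite directions where chance gives 22.6. By the larger of both p, the other genes above 0 in both lines with the smallest values were Col11a2, Hspg2, Rras2, Eln, Vangl1, Tma16, Stam2, Septin1 and Anxa1, and the genes below 0 in both were Abcc8, Crhr1, Cluh, Ryr1, Slc44a2, Fam174b, Lima1, Acbd3, Yae1d1 and Rdh11. Apart from Fcgr2b in Sca1 mice, none of these genes passed in either line, so no rise or fall was shown to be shared.

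As a list, the 100 genes with the smallest p among those lower in Sca1 knock-in mice had a median of -0.04 in Sca7 mice, with 73 of 100 below 0 (camera adjusted p = 0.00157; p = 0.246 with an estimated correlation). The 100 Sca1 genes with the smallest p upward had a median of 0.03 with 58 of 94 above 0 (adjusted p = 0.0576). In the other direction, the top Sca7 genes downward had a median of -0.04 in Sca1 mice with 58 of 99 below 0 (adjusted p = 0.0433; p = 0.0876 with an estimated correlation). The top Sca7 genes upward had a median of -0.00908 in Sca1 mice with 44 of 96 above 0, a negative mean and a test that pointed upward (adjusted p = 0.843). Without Sca1 knock-in replicate 4, Sca7 knock-in replicate 2 and Sca7 wild-type replicate 5 in turn, the first list lost its call, with medians of -0.0210, -0.0229 and -0.0219. The call of the Sca7 downward list ended without Sca1 knock-in replicates 2 and 4 (adjusted p = 0.0881 and 0.235), Sca1 wild-type replicates 2, 4 and 5 (0.144, 0.0517 and 0.0740), Sca7 wild-type replicates 1, 3, 4 and 5 (0.199, 0.0770, 0.168 and 0.985) and Sca7 knock-in replicates 2 to 5 (0.0835, 0.379, 0.736 and 0.0504), each in turn. The Sca1 upward list was called without Sca1 knock-in replicates 2, 5 and 6 (0.0429, 0.0425 and 0.0398), Sca1 wild-type replicate 6 (0.00875), Sca7 knock-in replicate 1 (0.00534) and Sca7 wild-type replicate 2 (0.000514). The Sca7 upward list was called without Sca7 knock-in replicate 1 (median 0.0588, adjusted p = 0.0138).

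The labels give the backcross of the lines, so the share of genes on the chromosome of the targeted gene was tested. Among the 33 genes called for the mean of both ages in Sca1 mice, 2 lay on the chromosome of Atxn1, F2r and Spock1 (6.06% of calls against 3.73% of tested genes, Fisher's exact p = 0.350). At 4 weeks, of 111 genes with an unadjusted p under 0.01, 11 lay there (9.91%, Fisher's exact p = 0.00280), and 4 of the 157 tested genes within 20 Mb of Atxn1 were among them (Fisher's exact p = 0.114). At the same threshold 10 of 269 genes lay there at 9 to 12 weeks (3.72%, Fisher's exact p = 1) and 19 of 382 in the mean of both ages (4.97%, Fisher's exact p = 0.212). In the Sca7 mice, 2 of 44 such genes lay on the chromosome of Atxn7 (4.55% against 3.59%, Fisher's exact p = 0.672). The lower threshold was used because no gene passed at 4 weeks or in Sca7 mice.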

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

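The tests of the Purkinje list at 9 to 12 weeks, of the choroid plexus arrays, of the chromosome of Atxn1, of the correlation between ages and of the grouping with 851 genes were chosen after these results were seen, and the other regroupings of the mice were planned.

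The Purkinje cell list was lower in Sca1 knock-in mice at 9 to 12 weeks, with 21 of 23 markers below 0. The tables argue against a single divergent array, since the list kept its direction without knock-in replicate 4 with an adjusted p of 1.22e-06, the highest over the arrays left out in turn (lowest 1.1e-12). They also argue against more choroid plexus, meningeal or blood vessel tissue in the knock-in arrays as the whole of the shift. Added tissue would dilute granule cell markers as much as Purkinje markers. Yet the mean of the Purkinje list minus that of the granule list differed by -0.324 (95% interval -0.471 to -0.176). The granule list mean itself differed by -0.000467 (95% interval -0.086 to 0.085), while the median of its genes lay below 0. A small part by dilution is therefore not excluded. The comparison of the Purkinje and granule lists replaced one by calls of the tissue lists after the values were seen. The medians of those tissue lists, -0.01, -0.23 and -0.02, decide nothing by themselves, since the call of meningeal fibroblasts did not hold with an estimated correlation (adjusted p = 0.362), in fry (0.237), without knock-in replicate 4 (0.6254) or without wild-type replicate 5 (0.235). A smaller share of Purkinje cell RNA may account for the shift, and it cannot be told apart from lower expression per cell: relative to the mean of the list, 1 marker departed downward (Doc2b) and 1 upward (Ebf1), and the bound of 3 departures that would have argued against it was set after the count was known, so an effect of the genotype by either route stays a hypothesis.

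Choroid plexus markers were lower in Sca1 knock-in mice at 4 weeks and higher in Sca7 knock-in mice, and in each case a single array carried most of its size. Less choroid plexus tissue in 1 dissected sample may account for both: without Sca1 knock-in replicate 1 the median was -0.0390 (adjusted p = 0.836), and without Sca7 wild-type replicate 4 it was 0.0273 (0.545). Ttr, whose values lay near the maximum of most arrays, was at 13.84 in that Sca1 array against 14.91 to 15.26 in the other Sca1 arrays. It was at 14.19 in that Sca7 array against 15.59 to 15.82. In the same arrays Kl was at 5.22 against 6.80 to 8.98 in the Sca1 arrays and at 4.71 against 7.79 to 8.69 in the Sca7 arrays. Neither call holds with an estimated correlation (adjusted p = 0.937 and 0.806), and whether a smaller difference remains in either line stays open.

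Of 111 genes with an unadjusted p under 0.01 at 4 weeks in Sca1 mice, 11 lay on the chromosome of Atxn1, and donor-strain DNA around the targeted gene may account for this, as the mice were backcrossed. At 9 to 12 weeks 10 of 269 genes lay there at the same threshold, 3.72% against 3.73% of tested genes (Fisher's exact p = 1). Among these 10 were Cmya5, F2r, Ly86 and Spock1 from the 11, and the rest were other genes. More genes reached the threshold elsewhere at that age, so the lower share decides neither for nor against donor DNA. Of the 11 genes, 10 had the same direction at 9 to 12 weeks (90.9%), but so did 90 of the 100 genes on other chromosomes (90%, Fisher's exact p = 1), and 6 of the 11 against 39 of the 100 also had a p under 0.05 there (Fisher's exact p = 0.348). In the older mice Cmya5 (-0.849), F2r (0.63), Ly86 (-0.651) and Spock1 (0.701) were about as far from 0 as at 4 weeks or farther, Fam8a1 (0.182), Snrnp48 (-0.255) and Yae1d1 (-0.315) were nearer, and Ccdc127 (-0.0417), which turned, Tbce (-0.0127), Slc6a3 (0.0313) and Htr1a (0.0637) were near 0. Fam8a1, Ly86, Snrnp48 and Spock1 lie within 20 Mb of Atxn1, and all of them kept their direction. The rest of the 11 lie farther away, the genes near 0 as well as Cmya5, F2r and Yae1d1. Donor DNA, an effect of the expanded allele and chance therefore cannot be told apart here. The genes elsewhere kept their direction as often, and the 11 are too few to compare sizes.

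Regrouping the mice showed how often another grouping gave as large a value, without correction for the number of such tests. For the mean of both ages in Sca1 mice, 2 of 100 groupings called as many genes as the real 33, the real one among them. Chance is unlikely at that level, although the other grouping called 851. That grouping set knock-in replicates 1, 3, 4 and 6 and wild-type replicates 2 and 6 against the rest, and 825 of its 851 genes were higher on 1 side and 819 of the 851 lay in the dimmer 50% of the probe sets. The first quartiles of the arrays were 2.78 to 2.91 on that side and 2.71 to 2.75 on the other, so the arrays differ by a structure at low values. It is found in both genotypes but is not balanced between them, as the higher side holds more knock-in than wild-type arrays. Without the dimmer 50% of probe sets that grouping called 0 genes and the real grouping 35. For the median of the Purkinje list in that mean (size 0.254), 1 of 100 groupings, the real one, was as far from 0, with 0.203 as the highest other. Chance is unlikely at that level, although the camera call of this list did not hold with an estimated correlation (adjusted p = 0.0792). For the correlation of fold changes between ages, 0.440, it was also 1 of 100, with 0.386 as the highest other, in a test chosen after the value was seen.

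Chance could not be excluded for the lists called in the mean of both ages (3, as many in 86 of 100 groupings, highest other 12) or for the difference between ages (9, in 18 of 100, highest other 14). It could not be excluded for the lists called in Sca7 mice (4, in 52 of 100, highest other 11), the correlation between lines (0.0524, in 60 of 100, highest other 0.206) or the median of the top Sca1 genes downward in Sca7 mice (size 0.0411, in 33 of 100, highest other 0.0823). For genes called, the real count was 0 for the difference between ages (highest other 851) and in Sca7 mice (highest other 14), so 100 of 100 groupings give as many by necessity and this says nothing about chance.

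The comparisons of 3 against 3 mice have 10 groupings, too few for a share under 0.05. At 4 weeks the real grouping called 0 genes with 1 as the highest other, so 10 of 10 give as many by necessity, and 3 lists with 11 as the highest other, in 9 of 10. At 9 to 12 weeks it called 14 genes with 10 as the highest other, in 1 of 10, and 10 lists with 16 as the highest other, in 2 of 10. For age in wild-type mice it called 41 genes with 0 as the highest other and 12 lists with 10 as the highest other, each in 1 of 10.

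Of 86 groups of 5 Sca7 mice tested for a value far from the others, 8 held one, where chance gives about 4.3. Knock-in replicate 1 stood apart in Irf9 at 7.07 (others 6.61 to 6.72) and in Epm2aip1 at 7.05 (7.43 to 7.51). Wild-type replicate 4 stood apart in Epm2aip1 at 7.65 (7.71 to 7.73), in Igfbp2 at 8.46 (9.95 to 10.48) and in the mean of the choroid plexus list at 5.37 (7.57 to 7.77). Igf1r was at 7.30 in wild-type replicate 1 (7.75 to 7.90). The mean of the metabotropic glutamate and calcium signalling list was 10.58 in wild-type replicate 2 (10.68 to 10.71) and 10.73 in knock-in replicate 5 (10.61 to 10.63).

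The genotype effect in Sca1 mice differed between ages for 9 lists in camera, by the difference itself. The medians of the difference were -0.172 for Purkinje cells, 0.0572 for granule cells, -0.117 for interneurons, -0.149 for Bergmann glia and astrocytes, -0.30 for myelin, 0.381 for choroid plexus, -0.160 for metabotropic glutamate and calcium signalling, -0.207 for channels and 0.0540 for oxidative phosphorylation. None of these held with an estimated correlation, where the adjusted p ran from 0.294 upward.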

How the results depend on the processing

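The tests without both 9-week mice, without Sca7 wild-type replicates 2 and 4 and knock-in replicate 5, and of the calcium signalling list without its Purkinje members were chosen after the results were seen, and the other alternatives were planned. Of the values that answer a comparison, 451 stayed the same under an alternative, 83 moved, 25 weakened, 10 strengthened and 12 turned. A test stayed the same if it kept its direction and its side of the threshold. A count did so if it changed by at most 1.5-fold or remained at 0, as several counts of genes did. The correlation between lines did so within its spread over regroupings, and a share of calls within its binomial interval. Of those of single genes and other values, 2534 stayed, 485 weakened, 97 moved, 28 turned and 20 strengthened. The Purkinje list at 9 to 12 weeks was called in 27 of 27 settings. Values near background limit what dim genes can show, and the cause of the changes was not tested except where fewer arrays or genes enter.

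Genes called at 9 to 12 weeks, in the mean of both ages and for age in wild type (14, 33 and 41) were 258, 375 and 209 with array weights, 28, 71 and 98 with exact age, and 33, 64 and 79 at an adjusted p under 0.1. At 9 to 12 weeks 5 passed under quantile normalization, 5 under median centring, 0 with only the 6 arrays compared (4 residual degrees of freedom are left), 79 with only the 12-week mice and 78 without both 9-week mice. In the mean of both ages 158 passed without both 9-week mice and 9 at 1.5-fold or more, and for age 26 passed under quantile normalization and 70 with every probe set on its own. With exact age all 14 and 33 were still called, and under quantile normalization 5 and 26. Replicate numbers were not used to pair the mice in the main fit, since not every sample correlates best with its own number. Whether they pair some mice stays open. The correlations of deviations between Sca1 mice of the same number were 0.413, 0.458 and 0.0133 for replicates 4, 5 and 6. For replicates 1, 2 and 3 they were -0.0535, -0.212 and 0.0444. Replicate 4 of each genotype was the only 9-week mouse of its group, so shared number and shared age cannot be told apart there. With the replicate as a block 6 genes passed at 9 to 12 weeks and 20 in the mean of both ages, 5 and 14 of them as before, Igfbp5 passed in that mean (adjusted p = 0.0406), and the age contrast could not be estimated. Pseudocounts do not apply to values deposited on a log scale.

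Lists called (3, 10, 3, 9, 12 and 4 at 4 weeks, 9 to 12 weeks, mean, difference, age and Sca7) were 0, 1, 0, 0, 0 and 0 with an estimated correlation, and 0, 5, 2, 0, 3 and 0 in fry. Without a filter 5 were called at 4 weeks and 10 in the mean. With the replicate block the granule cell list was called at 4 weeks (adjusted p = 0.0289). At 9 to 12 weeks 5 were called with the lower 50% left out, with only the 12-week mice and without both 9-week mice.

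In the mean of both ages Igfbp7 turned to 0.02 under quantile normalization, 0.0123 under median centring, 0.0273 with the mean of probe sets and 0.0111 without both 9-week mice, where Igfbp3 turned to -0.0351. In Sca7 mice Igfbp5 turned to 0.0197 under median centring and Igf1r to -0.0104 with the mean of probe sets. The test of the top Sca7 list upward in Sca1 mice turned, without a call, at a median of 0.0242 under median centring, -0.00183 without a filter and 0.00168 with array weights. The top Sca7 list downward lost its call at -0.0185 under quantile normalization, -0.0665 with the lower 50% left out, -0.0458 with array weights, -0.0557 with the block, -0.0330 without both 9-week mice and -0.0423 with an estimated correlation. The top Sca1 list downward lost it at -0.0411 with an estimated correlation and in fry, and at -0.0210 without both 9-week mice. The top Sca1 list upward was called at 0.0731 under median centring, 0.0261 without shared probe sets and 0.0497 without Sca7 wild-type replicates 2 and 4 and knock-in replicate 5.

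With each array left out in turn, genes called ran from 0 to 1 at 4 weeks (1 without knock-in replicate 1), 2 to 152 at 9 to 12 weeks (152 without knock-in replicate 4), 5 to 200 in the mean (200 without knock-in replicate 4), 0 to 1 for the difference and 0 to 65 for age. Lists called ran from 2 to 4, 5 to 10, 2 to 7, 3 to 11, 9 to 13 and, in Sca7 mice, 2 to 8. In the mean of both ages Igf1 ran from 0.126 to 0.353, Igf2 from -0.23 to -0.0652, Igfbp4 from 0.23 to 0.55, Atxn7 from -0.47 to -0.155, Igf1r from -0.11 to 0.0852, Igfbp2 from -0.38 to 0.0118, Igfbp3 from -0.0484 to 0.14 and Igfbp7 from -0.0928 to 0.0655. In Sca7 mice Atxn7 ran from -0.16 to 0.26, Igf1 from -0.16 to 0.00180, Igfbp2 from 0.0565 to 0.562, Igfbp3 from -0.147 to -0.0154, Igfbp4 from 0.0613 to 0.246, Igf1r from -0.0498 to 0.12 and Igfbp5 from -0.11 to 0.0547. The share of calls on the chromosome of Atxn1 ran from 0% to 7.69%, and the correlation between lines from -0.00747 to 0.116. Top Sca1 lists ran from -0.0665 to -0.0210 downward and 0.0122 to 0.0443 upward, and top Sca7 lists from -0.0618 to 0.00500 downward and -0.0393 to 0.0588 upward.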

Other observations

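No explanation is tested in this part, and all of its values were chosen after they were seen. Pituitary hormone transcripts stood out in a few arrays. Gh, which encodes growth hormone, was at 7.15 in Sca7 knock-in replicate 5 and at 5.18 in Sca7 wild-type replicate 2, where the median of the Sca7 arrays was 2.89. Prl, which encodes prolactin, was at 5.49 in Sca7 knock-in replicate 5, where the highest of the other Sca7 arrays was 3.06. Pomc, the precursor of corticotropin, was at 3.78 in the same array, with 2.98 as the highest of the others. In Sca1 mice Gh was at 5.47 in wild-type replicate 4, with 3.72 as the highest of the others.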
